A study of Mus musculus with 3 samples.

How the data were processed

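RNA was isolated with a Picopure kit from ZsGreen-positive cells sorted from digested hindlimb muscle of Pax7-ZsGreen mice, and libraries followed Illumina standard protocols, per the labels. The 3 libraries were assigned to 1 group from their titles, which also give the replicate numbers 1 to 3. Per the submitters' processing notes, the genome build was mm10 and the tools were CASAVA 1.8, Bowtie 0.12.9 and RSEM 1.2.3; the role and settings of each are not given in the sources used here. RNA selection, strand setting, read length and gene annotation are likewise not given.

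The authors deposited 1 table of TPM (transcript shares corrected for transcript length), with 20308 gene symbols and 1 column per library. Each deposited TPM column sums to the same total, between 999999.85 and 1000000.3, and the table lists 0 symbols that start with mt-. The name the authors gave the table says that mitochondrial genes were left out and that TPM was renormalised, so values are relative to the genes in the table and higher than in a table with mitochondrial genes. TPM divides by transcript length and by the library total, so a level is a share of the measured transcripts, not an amount per cell. It keeps no read totals: depth is unknown, and no counting interval or detection limit is given. A value of 0 can be a failed estimate, since genes used by every cell, such as Rps27, are listed at 0, so such genes are described as listed at 0. In the table, 27 symbols had been turned into dates by a spreadsheet, and these genes are not named here.

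Gene positions are from the GENCODE M21 annotation of GRCm38 (the same assembly as mm10), in which 20157 of the symbols had a position. Exon length is the union of a gene's exons. Reads from near-identical genes can be divided wrongly, so the share of 31-base words of a gene's longest transcript that occur in the longest transcript of another annotated gene was computed.

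Levels were tested on log2(TPM + 0.1), a scale that understates folds of low genes. For each of 12822 genes above 0 in at least 1 library, limma 3.58.1 in R 4.3.3 fitted an intercept and tested it against log2(1 + 0.1), two-sided, with empirical Bayes moderation, a variance trend and Benjamini-Hochberg adjustment over all genes tested (adjusted p threshold 0.05). A gene is called above or below 1 TPM when it passed. Variable genes were sought among 11318 genes of at least 1 TPM on average, as the ratio of residual variance to limma's trended prior variance (F test, Benjamini-Hochberg). Gene pairs (14) were compared as log2 ratios within each library with limma over the pairs and an exact sign-flip permutation test, two-sided. The satellite cell list was set against 9 other lists as the difference of mean log2 levels per library, with the same exact test. Each of the 27 gene lists was described by its members above and below 1 TPM and by the percentile of its median among 10000 random lists drawn from all genes in the table. The spread of a list's mean between libraries was set against 10000 random lists matched on level in 20 bins, for lists with at least 5 members of at least 1 TPM. Genes are not replicates, so these percentiles describe the 3 libraries only. Correlations between libraries are across genes and carry no p.

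The lists, pairs, tests and alternatives were fixed before the data were examined. The lists covered satellite cell identity, quiescence and activation; cell cycle; myogenic differentiation and fusion; mature fibre; the dissociation response; fibro-adipogenic, endothelial, leukocyte, erythroid, pericyte and smooth muscle, Schwann, tendon and other-organ markers; Hox genes; limb and head position factors; Notch; Wnt; receptors; matrix; Polycomb and Trithorax; glycolysis; fatty acid oxidation; sex-linked, housekeeping and ribosomal protein genes. Listed symbols without a row in the table were not used. The genes named are, by rule, the 20 with the highest mean; the 3 highest members of each list; all members of satellite cell identity, differentiation and fusion, position factors and sex-linked genes, and Hox genes above 1 TPM; both genes of each pair; and up to 10 variable genes of at least 5 TPM with the largest range. Other genes are said to have been chosen after their values were seen. Some genes that the rule names are not reported here.

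The level test was tested on simulated data with 12720 genes. It called above 1 TPM 10%, 32%, 86% and 100% of genes planted at 2, 4, 8 and 16 times that level, with 50 genes at each. Of genes planted at the threshold it called 5% above and 5% below. The noise was normal on the log2 scale, and the frequent zeros of low genes were not modelled separately. The rates may therefore differ from the power of the test in these data. The variable gene test, simulated over 11318 genes, recovered 0% of 200 genes at 10 times and at 30 times the SD. The 200 genes were planted together and so entered the prior. A robust prior, added after seeing the data, recovered 30% and 71.5%, and also called 0.423% and 0.504% of genes with no added spread.

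The alternatives were pseudocounts of 0.01 and 1, a filter at a mean of 0.1 TPM, no filter, scaling by median ratio size factors, TPM rescaled without ribosomal protein genes, no variance trend, thresholds of 0.5 and 2 TPM, list medians in place of means, and leaving out each replicate. A robust prior and a minimum of 100 TPM for agreement between libraries were added after seeing the data. Groups of other splits were not formed, since there is 1 group. Figures were drawn with matplotlib 3.10.9, and exon lengths and 31-base words were computed with Python 3.11.15 and numpy 2.4.6.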

Results

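Transcript levels were measured by RNA sequencing in satellite cells, the resident stem cells of skeletal muscle, from hindlimb muscle of mice aged 3 months. The mice carried a reporter that places the green fluorescent protein ZsGreen under control of Pax7, the transcription factor that marks these cells. About 200000 ZsGreen-positive cells per sample were sorted after enzymatic digestion of muscle pooled from several animals. The 3 libraries formed 1 group, so the data describe this cell population and contain no comparison between conditions. Because the sort used the Pax7 reporter, Pax7 transcript is no independent finding. Values are TPM (transcript shares corrected for transcript length and scaled to a common total) for 20308 genes, given as mean ± SD over the 3 libraries (n = 3) unless each library is listed. The deposited values keep no read totals, so the depth of each library is unknown. The labels do not say whether the libraries came from separate pools of animals, so p-values measure only the spread between these samples, which may be technical. The sample labels name the tibialis anterior as the tissue, whereas the series description names hindlimb muscles.

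The most abundant transcripts of the sorted cells encoded chaperones, a chemokine and the translation machinery. Hspa8, a constitutive heat shock chaperone (chromosome 9, 40800984 to 40810087, GRCm38), stood first at 15985 ± 943 TPM. Cxcl1, a neutrophil chemokine (chromosome 5, 90891241 to 90893115), stood second at 15278 ± 1016 TPM. Other abundant genes were the elongation factor Eef1a1 at 7945 ± 568 TPM, the splicing factor Srsf5 at 7754 ± 297 TPM, Rps16 at 7463 ± 214 TPM and the chaperone Hsp90ab1 at 6827 ± 564 TPM. Emp1, an epithelial membrane protein, reached 6423 ± 561 TPM. The muscle gene Asb5 reached 5637 ± 460 TPM and the endoplasmic reticulum chaperone Hspa5 reached 5539 ± 131 TPM. Also among the 20 most abundant were Ddx5, Rpl26, Tpt1, Rpl19, Hsp90aa1, Ubb, Rps12, Gnas, Hnrnpa2b1 and Cd63, between 4277 and 5731 TPM. Many of these genes share 31-base words with other annotated genes, so their levels may depend on how shared reads were divided. The gene annotation used for the deposited values is not given, so this dependence was not established. The share was 79.9% for Rpl19, 72.3% for Eef1a1, 62.9% for Hsp90aa1, 59.4% for Hspa8, 55.02% for Rpl26, 54.1% for Ubb, 44.5% for Rps16, 42.9% for Tpt1, 33.4% for Ddx5 and 32.4% for Rps12.

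The 10 most abundant genes of each library held 8.63% ± 0.068 of all TPM and the 100 most abundant held 33.6% ± 0.627. Ribosomal protein genes held 14.2% ± 0.275, with 79 of 83 members above 1 TPM, 3 listed at 0 in all libraries and a list median of 1494 TPM. All 10 housekeeping genes were above 1 TPM, with a median of 935 TPM. Of the 12822 genes above 0 in at least 1 library, 7796 lay above 1 TPM, 279 lay below it and 4747 were not decided by limma's moderated test with Benjamini-Hochberg adjustment. Among those above, 6586 averaged at least 10 TPM, 1544 at least 100 TPM and 180 at least 1000 TPM. The count below 1 TPM rested on the pseudocount and on having all 3 libraries: it was 3 instead of 279 with a pseudocount of 0.01, 0 for genes with a mean of at least 0.1 TPM, and 0 when any 1 replicate was left out. The remaining 7486 genes were listed at 0 in all 3 libraries and were not tested.

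The sorted cells carried the transcripts that define satellite cells. Of 15 satellite cell identity genes, 14 were above 1 TPM (limma, Benjamini-Hochberg), with a list median of 154 TPM. That median lay at percentile 100 of 10000 random lists of the same size. The random lists also drew on the 7486 genes at 0 in all libraries, so high percentiles were not particular to this list. The fibro-adipogenic list reached 99.83 and the endothelial list 99.02. Pax7 (chromosome 4, 139737062 to 139833528) averaged 51.4 ± 5.22 TPM. Its paralogue Pax3, which shares its role in muscle precursors, averaged 11.8 ± 2.70 TPM, and Pax7 exceeded Pax3 by 2.13 ± 0.315 on the log2(TPM + 0.1) scale (4.38-fold, limma adjusted p = 0.00167, higher in 3 of 3 libraries). The heparan sulphate proteoglycan Sdc4 was the highest member at 4135 ± 192 TPM, while the related Sdc3 averaged 9.03 ± 0.529 TPM. Desmin (Des), the muscle intermediate filament, averaged 1164 ± 17.9 TPM. Transcripts of surface proteins used to isolate satellite cells were also present; protein was not measured. Vcam1 averaged 467 ± 44.0 TPM, Cxcr4 383 ± 50.3 TPM, Itga7 207 ± 6.39 TPM, Cdh15 120 ± 23.9 TPM and Cd34 67.4 ± 20.02 TPM. Chodl averaged 508 ± 49.3 TPM, Chrdl2 263 ± 6.70 TPM, Fgfr4 154 ± 27.1 TPM and Calcr 31.5 ± 3.45 TPM. Msx1, at 2.08 ± 0.977 TPM, was the member not decided.

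Among the myogenic regulatory factors, Myod1 was far above the others in these digested and sorted cells. Myod1 (chromosome 7, 46376474 to 46379099), the factor of committed myoblasts, averaged 1240 ± 74.5 TPM. Myf5 (chromosome 10, 107482908 to 107486134) averaged 104 ± 24.2 TPM. Myod1 exceeded Pax7 24.1-fold (limma adjusted p = 0.000465) and Myf5 12.2-fold (limma adjusted p = 0.000465), in 3 of 3 libraries each. Myog, the factor that drives terminal differentiation (chromosome 1, 134289989 to 134292548), gave 40.7, 52.6 and 9.19 TPM in replicates 1, 2 and 3. Myod1 exceeded Myog by 5.51 ± 1.41 on the log2 scale (45.7-fold, limma adjusted p = 0.0027, 3 of 3 libraries), and by 4.70 without replicate 3. Myf6 was listed at 0 in replicates 1 and 3 and at 8.42 TPM in replicate 2. For every pair ratio in which the libraries shared a direction, the exact sign-flip permutation p was 0.25, the smallest that 3 libraries allow, so the adjusted values rest on limma's pooled variance over the 14 pairs.

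Differentiation and fibre genes were above 1 TPM in part. Of 13 differentiation and fusion genes, 4 were above 1 TPM and 3 were listed at 0 in all libraries (limma, Benjamini-Hochberg), with a median of 2.81 TPM (percentile 55.4 of random lists). The 4 were Myog, the acetylcholine receptor subunit Chrna1 at 32.1 ± 8.19 TPM, cardiac actin Actc1 at 7.04 ± 1.60 TPM and Mef2c at 6.70 ± 4.13 TPM. Mef2c was not past the threshold without replicate 1 (limma adjusted p = 0.129). The fusion gene Gm7325 (also called Mymx), the perinatal myosin Myh8 and Mybph were listed at 0 in all 3 libraries, and Tmem8c (also called Mymk) reached 3.41 TPM in replicate 2 and was at 0 in replicates 1 and 3. Myl4 was listed at 0, 19.8 and 15.1 TPM in replicates 1 to 3, Myh3 at 0, 1.1 and 1.67, Chrng at 0, 2.52 and 1.55, and Tnnt2 at 11.4, 0 and 0.80. Of 21 mature fibre genes, 11 were above 1 TPM, or 10 adjusted over the list alone, with a median of 11.1 TPM (percentile 95.5). The highest were slow troponin T (Tnnt1) at 139 ± 67.0 TPM, alpha-actinin 3 (Actn3) at 80.0 ± 14.6 TPM and fast troponin C (Tnnc2) at 7, 16.3 and 77.2 TPM in replicates 1 to 3. In each library the satellite cell list averaged higher than the fibre list, by 4.76 ± 0.446 on the log2 scale (exact sign-flip permutation p = 0.25). For the other lists, the number of members above 1 TPM was the same when adjusted over the list alone. One ribosomal protein gene was below 1 TPM only in that adjustment.

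Genes of the quiescent and of the activated state were both abundant. Of 15 quiescence genes, 14 were above 1 TPM with a median of 70.2 TPM (percentile 99.99 of random lists), and Foxo3, at 8.03, 6.17 and 0.15 TPM, was not decided. Its highest members were the receptor Notch3 at 219 ± 10.3 TPM, the Notch target Hey1 at 147 ± 44.5 TPM and the collagen Col5a1 at 147 ± 8.75 TPM. Of these 15 genes, 8 are also held by another list. All 11 activation genes were above 1 TPM (limma, Benjamini-Hochberg), with a median of 1011 TPM (percentile 100). Ornithine decarboxylase Odc1 averaged 3606 ± 6.19 TPM, and the nucleolar proteins Npm1 and Ncl averaged 3172 ± 40.7 and 2300 ± 296 TPM. Odc1 shares 52.0% of its 31-base words with other genes and Npm1 45.5%. The transcription factor Myc averaged 1011 ± 69.4 TPM and Runx1 339 ± 32.2 TPM, both named after their values were seen. The activation list contains Myod1, and its members are also used in many growing cells. No undissociated sample was measured, so the levels of these genes before digestion and sorting are unknown.

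Cell cycle genes stood at lower levels than the activation genes. Of 22 S, G2 and M phase genes, 10 were above 1 TPM, 2 below it and 1 was at 0 in all libraries, with a median of 4.54 TPM (percentile 74.0). The replication clamp Pcna averaged 393 ± 25.2 TPM, and the helicase subunit Mcm7 averaged 32.0 ± 11.5 TPM. Pcna shares 38.0% of its 31-base words with other genes and Mcm7 37.6%. The 2 members below 1 TPM were Ccnb1, at 0, 0 and 0.17 TPM, and Cdk1, at 0, 0.12 and 0 TPM (limma adjusted p = 0.0398 and 0.0316), and both calls were lost when any 1 replicate was left out. They were named after their values were seen. Birc5, another S, G2 and M phase gene of the list, was at 0.09, 21.2 and 59.3 TPM and was not decided. Among cell cycle inhibitors, Cdkn1a (p21) averaged 300 ± 27.1 TPM, Cdkn1b (p27) 126 ± 17.0 TPM and Cdkn1c (p57) 90.6 ± 5.58 TPM. Cdkn1b exceeded the cyclin Ccnd1, at 31.2 ± 8.30 TPM, 4.09-fold (limma adjusted p = 0.00438, 3 of 3 libraries). Cdkn1a exceeded Cdkn1c 3.30-fold (limma adjusted p = 0.00167, 3 of 3 libraries).

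**Figure D1:**
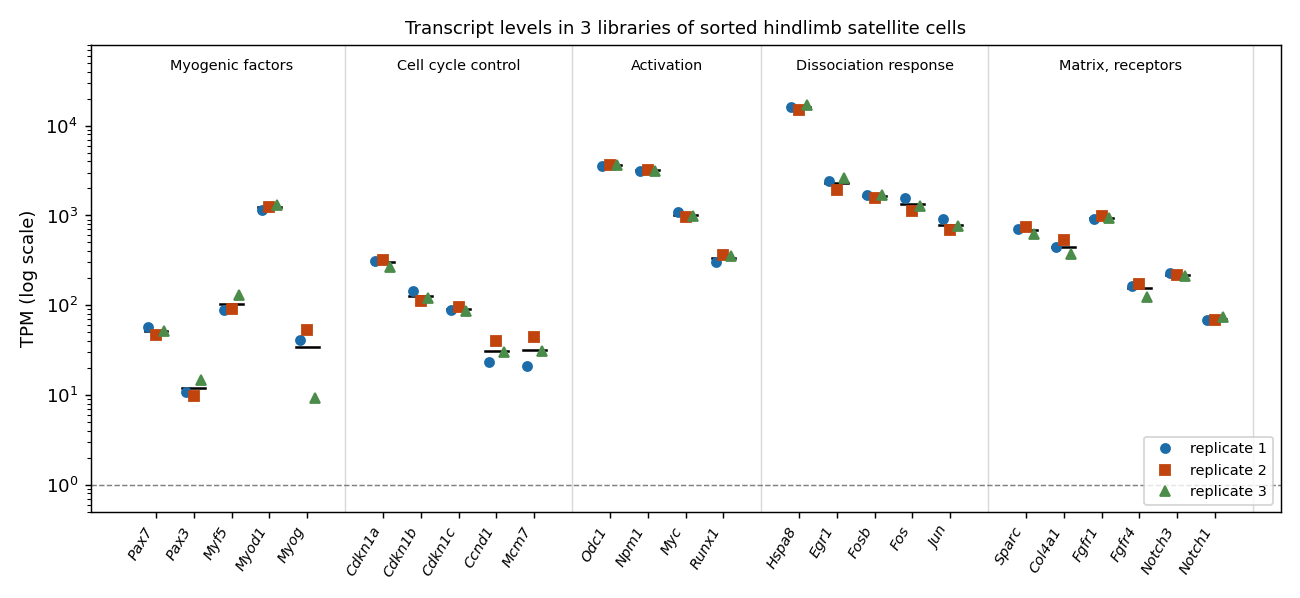
TPM on a log axis for 25 genes grouped by function, with 1 point per library and a black line at the mean of the 3 libraries; the dashed line marks 1 TPM. Myod1 at 1240 TPM lies above Pax7 at 51.4 TPM and Myog at 34.2 TPM, and replicate 3 of Myog (9.19 TPM) lies below the other libraries.

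Immediate-early and stress genes, which rise when tissue is dissociated, were high in all 3 libraries. All 30 listed genes in the table were above 1 TPM (limma, Benjamini-Hochberg), with a median of 493 TPM (percentile 100), and together they held 4.18% ± 0.254 of all TPM. Hspa8 (15985 ± 943 TPM), a constitutive chaperone, and Hsp90aa1 (5134 ± 333 TPM) were the highest. The list summed to 42594, 38982 and 43870 TPM in replicates 1 to 3, so these chaperones carried a large part of it. No undissociated sample was measured, so a rise was not tested. The inducible chaperone Hspa1b followed at 2329 ± 540 TPM. Hspa1b shares 68.0% of its 31-base words with other genes. Among the transcription factors, Egr1 averaged 2326 ± 363 TPM, Fosb 1655 ± 82.1 TPM, Fos 1335 ± 229 TPM and Jun 792 ± 117 TPM. These 4 were named after their values were seen.

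Lists of markers of the other cells of muscle averaged below the satellite cell list on the log2 scale. Single markers did not all lie below it. Fabp4, Gsn, Col3a1, Dpt and the erythroid marker Hba-a2 were among those whose means exceeded the satellite cell list median of 154 TPM. Of 15 fibro-adipogenic progenitor genes, 9 were above 1 TPM (limma, Benjamini-Hochberg), with a median of 33.6 TPM (percentile 99.83). Gelsolin (Gsn) averaged 888 ± 104 TPM, the collagen Col3a1 585 ± 29.9 TPM and dermatopontin (Dpt) 572 ± 16.7 TPM. Pdgfra, the receptor used to sort those cells, was at 4.98, 0.11 and 0.06 TPM and was not decided. It was named after its values were seen. Of 14 endothelial genes, 13 were above 1 TPM, with a median of 22.8 TPM (percentile 99.0). Fabp4, a fatty acid carrier of capillaries and adipocytes, averaged 1898 ± 629 TPM, while the claudin Cldn5 averaged 46.2 ± 20.3 TPM and Pecam1 40.5 ± 18.1 TPM. The satellite cell list exceeded these lists in every library, by 2.58 ± 0.786 (fibro-adipogenic) and 2.49 ± 0.44 (endothelial) on the log2 scale.

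Tendon, mural and nerve sheath markers were also measured. Of 7 tendon genes, 6 were above 1 TPM, led by Thbs4 at 154 ± 47.9 TPM, Fmod at 49.2 ± 15.0 TPM and Comp at 27.1 ± 10.4 TPM (list median 20.1 TPM, percentile 93.9). Of 10 pericyte and smooth muscle genes, 6 were above 1 TPM and 1 below, with Acta2 at 95.04 ± 8.65 TPM, Tagln at 84.0 ± 23.2 TPM and Rgs5 at 64.4 ± 30.03 TPM (median 11.9 TPM, percentile 89.2). The member below was Cnn1, at 0, 0 and 0.18 TPM (limma adjusted p = 0.0414), a call lost when any 1 replicate was left out. It was named after its values were seen. Of 10 Schwann cell genes, 6 were above 1 TPM, with Pmp22 at 86.4 ± 30.98 TPM and Mbp at 45.0 ± 11.7 TPM (median 6.82 TPM, percentile 76.4). The satellite cell list exceeded the tendon list by 3.20 ± 0.702, the pericyte list by 4.01 ± 0.47 and the Schwann cell list by 4.22 ± 0.496 on the log2 scale, in 3 of 3 libraries each.

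Blood cell markers were above 1 TPM in part. Of 18 leukocyte genes, 6 were above 1 TPM and 4 were listed at 0 in all libraries (median 6.64 TPM, percentile 83.4). Cd74, the invariant chain of antigen presentation, averaged 153 ± 17.2 TPM, lysozyme Lyz2 70.1 ± 16.1 TPM and S100a9 27.4 ± 21.4 TPM. Lyz2 shares 32.8% of its 31-base words with other genes. Of 6 erythroid genes, 2 were above 1 TPM and 3 were listed at 0 (median 2.63 TPM, percentile 47.0). Among haemoglobin genes, Hba-a2 was at 167, 75.7 and 338 TPM and Hbb-bs was at 148, 47.8 and 115 TPM. Hbb-bt was listed at 0, 15.8 and 0 TPM, and these genes share at least 59.4% of their 31-base words with other genes. The satellite cell list exceeded the leukocyte list by 6.02 ± 0.537 and the erythroid list by 6.57 ± 0.431 on the log2 scale. Of 17 markers of other organs, 11 were listed at 0 and 1 was above 1 TPM, the pluripotency gene Nanog at 13.0 ± 1.89 TPM. Nanog shares 9.995% of its 31-base words with other genes, and the source of its reads was not tested. The list was meant as background, so a background gene can be called above 1 TPM at this level. The other-organ list lay 9.30 ± 0.366 below the satellite cell list, with a median of 0 TPM (percentile 6.56). Alb, a liver gene of that list, averaged 1.95 ± 0.688 TPM and was not decided. For each of these 9 lists the exact sign-flip permutation p was 0.25, the smallest possible.

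**Figure D2:**
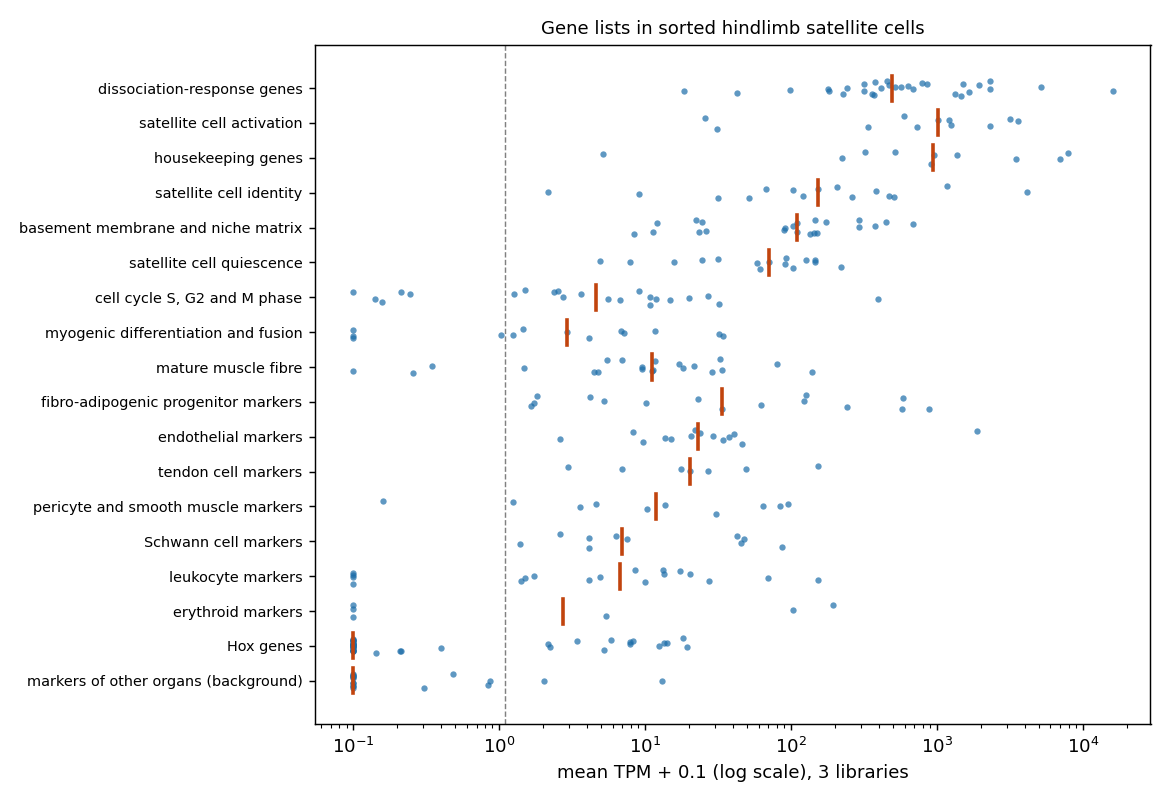
Mean TPM + 0.1 over the 3 libraries (log axis) of each member of 18 gene lists, 1 point per gene, with an orange line at the list median and a dashed line at the 1 TPM threshold. Activation genes have a median of 1011 TPM and satellite cell identity genes one of 154 TPM, whereas the medians for Hox genes and other organs are at 0.

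Genes that record limb and head position gave a partial pattern. Of 38 Hox genes, 7 were above 1 TPM, 1 below, 21 were listed at 0 in all libraries and 9 were not decided (limma, Benjamini-Hochberg), with a median of 0 TPM (percentile 1.74). Those above were in the HoxA and HoxC clusters: Hoxa7 at 19.2 ± 2.01 TPM, Hoxc4 at 18.2 ± 10.3 TPM, Hoxa10 at 14.1 ± 10.6 TPM, Hoxa5 at 13.4 ± 8.99 TPM, Hoxc10 at 12.4 ± 13.1 TPM, Hoxc11 at 8.11 ± 4.77 TPM and Hoxa9 at 7.77 ± 4.86 TPM. Hoxa9 was no longer past the threshold without replicate 1 (limma adjusted p = 0.0769) or 3 (0.0508), nor Hoxc10 without replicate 3 (0.115). The member below was Hoxb9, at 0.13, 0 and 0 TPM (limma adjusted p = 0.0333), a call lost when any 1 replicate was left out. It was named after its values were seen.

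Of 13 position factors, 6 were above 1 TPM and 3 were listed at 0 in all libraries, with a median of 4.11 TPM (percentile 65.9). Those above included Msc at 107 ± 42.6 TPM, Lbx1 at 13.7 ± 1.39 TPM, Pax3 and Six4 at 6.90 ± 3.92 TPM. Six4 was not past the threshold without replicate 1 (limma adjusted p = 0.0718) or 3 (0.0741). Tbx5, a forelimb gene, Pitx1, a hindlimb gene, and Tcf21 were listed at 0 in all 3 libraries. Tbx4, a hindlimb gene, was listed at 5.72, 0 and 3.71 TPM and was not decided. The ratio of Tbx4 to Tbx5 missed the threshold (limma adjusted p = 0.073, exact sign-flip permutation p = 0.5), and without replicate 2, where Tbx4 was at 0, it passed (adjusted p = 0.00342). Meox2 averaged 4.11 ± 2.07 TPM and Isl1 2.84 ± 2.88 TPM, and Tbx1 was listed at 0, 0 and 7.38 TPM, none of them decided.

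Receptors of the satellite cell niche were well represented. Of 21 growth factor and cytokine receptors, 16 were above 1 TPM, with a median of 37.7 TPM (percentile 99.97). Fgfr1 averaged 939 ± 32.7 TPM and exceeded Fgfr4 6.15-fold (limma adjusted p = 0.00107, 3 of 3 libraries). The cytokine receptor subunit Il6st averaged 279 ± 22.1 TPM. The TGF-beta receptor Tgfbr1, at 107 ± 15.2 TPM, exceeded Tgfbr2, at 38.9 ± 1.81 TPM, 2.73-fold (limma adjusted p = 0.00329, 3 of 3 libraries). In the Notch pathway, 11 of 19 genes were above 1 TPM, with a median of 15.8 TPM (percentile 98.3). Notch3 exceeded Notch1, at 70.2 ± 3.08 TPM, 3.11-fold (limma adjusted p = 0.00167, 3 of 3 libraries), and the ligand Jag1 averaged 135 ± 6.80 TPM. Of 19 Wnt receptors and response genes, 11 were above 1 TPM and 1 below (median 7.95 TPM, percentile 88.5). Beta-catenin (Ctnnb1) averaged 812 ± 46.5 TPM, the co-receptors Lrp6 and Lrp5 83.7 ± 7.61 and 28.0 ± 8.46 TPM. The member below was Lgr5, at 0, 0.18 and 0 TPM (limma adjusted p = 0.0414), a call lost when any 1 replicate was left out. It was named after its values were seen.

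Matrix and metabolic genes completed the profile. All 22 basement membrane and niche matrix genes were above 1 TPM (limma, Benjamini-Hochberg), with a median of 109 TPM (percentile 100), led by Sparc at 688 ± 68.6 TPM, Col4a1 at 447 ± 78.3 TPM and Col5a2 at 379 ± 32.4 TPM. All 14 glycolysis genes were above 1 TPM, with a median of 136 TPM (percentile 100). Gapdh averaged 954 ± 175 TPM, Pkm 656 ± 90.5 TPM and Aldoa 553 ± 20.2 TPM. Pkm shares 50.9% of its 31-base words with other genes and Gapdh 30.65%. Hexokinase 2 (Hk2), at 249 ± 13.6 TPM, exceeded Hk1, at 80.3 ± 16.1 TPM, 3.14-fold (limma adjusted p = 0.00214, 3 of 3 libraries). Of 16 fatty acid oxidation genes, 11 were above 1 TPM and 1 below, with a median of 30.7 TPM (percentile 99.82). Acadvl averaged 163 ± 11.5 TPM, Etfa 107 ± 25.5 TPM and Etfb 104 ± 39.9 TPM. Etfb shares 68.0% of its 31-base words with other genes. The member below was the nuclear receptor Ppara, at 0, 0 and 0.17 TPM (limma adjusted p = 0.0398), a call lost when any 1 replicate was left out. It was named after its values were seen. The liver-type carnitine palmitoyltransferase Cpt1a exceeded the muscle-type Cpt1b 5.32-fold (limma adjusted p = 0.0154, 3 of 3 libraries), which missed the threshold without replicate 2 (adjusted p = 0.0541). Cpt1b, at 4.66 ± 3.09 TPM, shares 93.7% of its 31-base words with other genes.

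Of 20 genes listed as Polycomb and Trithorax regulators, which maintain repressed and active chromatin, 17 were above 1 TPM. The list median was 19.4 TPM (percentile 99.3), and the list also holds Suv420h1, which belongs to neither group. The histone H3K27 demethylase gene Kdm6b averaged 277 ± 19.6 TPM, Suv420h1 99.8 ± 31.5 TPM and Suz12 70.5 ± 5.58 TPM. The methyltransferase genes Ezh1, at 19.5 ± 3.99 TPM, and Ezh2, at 22.3 ± 10.7 TPM, did not differ by more than the spread between libraries (log2 ratio -0.08 ± 0.966, limma adjusted p = 0.864, exact sign-flip permutation p = 1). The sign of that ratio turned when a library was left out, which gave values from -0.54 to 0.42. Of the sex-linked genes, all 4 in the table, which lie on the Y chromosome, were above 1 TPM (limma, Benjamini-Hochberg): Ddx3y at 618 ± 25.9 TPM, Eif2s3y at 77.2 ± 7.43 TPM, Uty at 21.1 ± 3.27 TPM and Kdm5d at 8.47 ± 0.133 TPM. Xist was not analysed here.

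Agreement between the libraries depended on the level of the gene. Across 12822 genes, which are not independent replicates, Pearson's r of log2(TPM + 0.1) was 0.757, 0.757 and 0.764 for the 3 pairs of libraries, and Spearman's rank correlation was 0.853, 0.843 and 0.853. Among 1545 genes of at least 100 TPM, a limit chosen after seeing the data, r was 0.947, 0.943 and 0.969. The median SD between libraries was 0.0999 on the log2 scale above 1000 TPM, 0.636 between 10 and 20 TPM and 2.80 between 1 and 2 TPM. In the last of these bins, 81.5% of the genes were listed at 0 in at least 1 library, against 0.781% between 20 and 50 TPM.

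**Figure D3:**
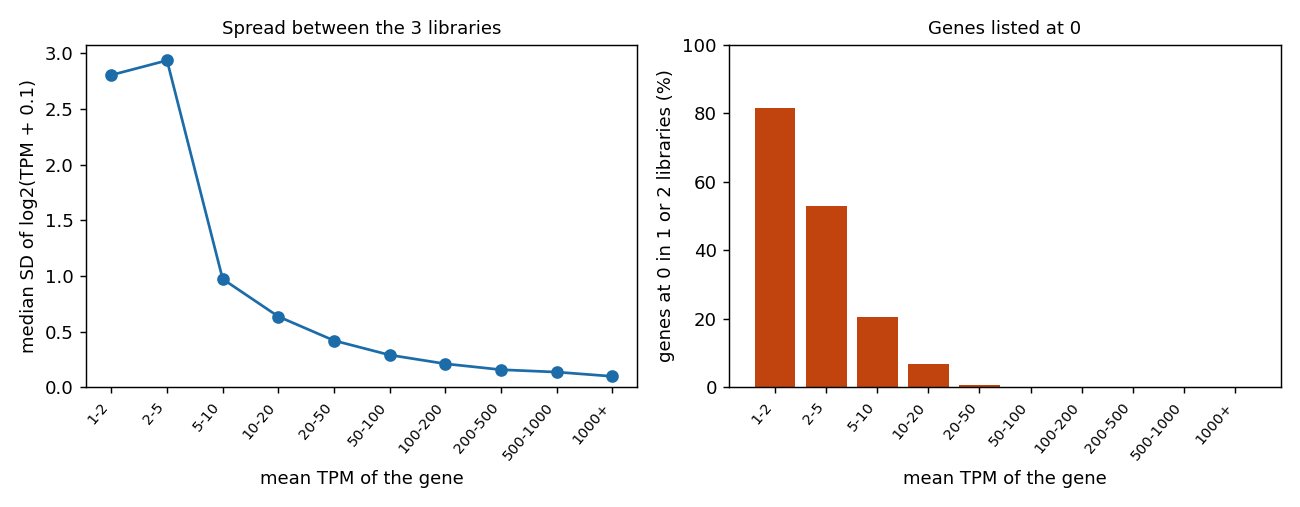
Left, median SD over the 3 libraries of log2(TPM + 0.1) in bins of mean TPM; right, percentage of the genes in each bin listed at 0 in 1 or 2 libraries. Median SD was 2.80 at 1 to 2 TPM, 2.935 at 2 to 5 TPM and 0.0999 above 1000 TPM.

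Of 11318 genes tested, 2 varied between libraries by more than genes of their level (F test on limma variances with Benjamini-Hochberg, adjusted p = 0.0231 each). Gstp1, a glutathione transferase, was listed at 0, 167 and 184 TPM, and Timm10, a mitochondrial import chaperone, at 7.62, 253 and 173 TPM. Gstp1 shares 67.5% of its 31-base words with other genes and Timm10 0%. At an unadjusted p under 0.05 there were 629 genes. With a pseudocount of 0.01, or with no variance trend, 0 genes passed, so both calls were lost. In simulated data the test recovered 0% of 200 genes given 10 times the SD. Those genes were planted together and entered the prior, so the power to find a few such genes is unknown. Gstp1 and Timm10 passed at 85.8 and 79.8 times the prior variance. Without replicate 1, 2 or 3 the count was 57, 29 or 47, so the number of variable genes is not settled by 3 libraries. Lists whose mean varied most against level-matched lists were the growth factor and cytokine receptors (percentile 96.94), activation genes (95.22) and fibro-adipogenic markers (94.62). These are the highest of many lists ranked, and the percentiles were not adjusted for the number of lists. The receptor list gave 60.99, 59.5 and 12.38 without replicate 1, 2 and 3, the fibro-adipogenic list 97.93, 82.88 and 28.16, and the activation list 86.59, 76.43 and 99.08.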

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

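The robust prior and the minimum of 100 TPM for agreement between libraries were chosen after seeing the data, and the other alternatives were planned. No paired analysis was possible because the study has only 1 group. The number of genes above 1 TPM (7796) stayed within 1.5 times under all 12 alternatives, from 7169 at a threshold of 2 TPM to 8236 at 0.5 TPM, and all 323 recomputed list counts did too. Of the recomputed levels of named genes, 1342 kept their direction and side of the threshold, 7 no longer passed it, 6 newly passed it and 15 changed sign. Depth is unknown, so what it limits was not measured. Where not stated, the cause was not tested.

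The 279 genes below 1 TPM became 3 with a pseudocount of 0.01, 451 with a pseudocount of 1, 0 with a mean of at least 0.1 TPM (the filter removes them), 8056 with no filter (which adds the genes at 0 in all libraries), 163 without ribosomal protein genes, 478 with no variance trend, 0 at a threshold of 0.5 TPM, 598 at 2 TPM and 0 to 0 without 1 replicate. The 2 variable genes became 0 with a pseudocount of 0.01 or no variance trend, 16 with the robust prior and 29 to 57 without 1 replicate.

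The satellite cell list minus the fibre list was 5.28 with a pseudocount of 0.01, 4.06 with a pseudocount of 1 and 4.30 by medians (log2). Minus leukocyte markers it was 7.22 and 4.70 with those pseudocounts, minus erythroid markers 8.59 and 4.58 (9.39 by medians), and minus other organs 11.80 and 6.70 (10.61 by medians). Minus pericyte and Schwann markers it was 3.497 and 3.684 with a pseudocount of 1. All of these kept their sign. Median Pearson r between libraries was 0.701 at a mean TPM of at least 1.

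Spread percentiles crossed 95 as follows. Activation genes (95.22) gave 94.24 with a pseudocount of 1, 93.15 with library scaling and 76.43 to 99.08 without 1 replicate. Receptors (96.94) gave 93.37 with a pseudocount of 1 and 12.38 to 60.99 without 1 replicate. Fibro-adipogenic markers (94.62) gave 98.42 with a pseudocount of 1 and 28.16 to 97.93 without 1 replicate. Cell cycle genes (90.18) gave 7.67 to 95.15 and glycolysis genes (89.51) 54.17 to 96.24 without 1 replicate.

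Without 1 replicate, the log2 ratio of Ezh1 to Ezh2 ran from -0.54 to 0.42, that of Tbx4 to Tbx5 from 2.63 to 5.56 and that of Cpt1a to Cpt1b from 1.83 to 2.97. Levels that changed sign belonged to genes that the reported test had not decided (log2 over 1 TPM). Tbx4 (0.25) gave -0.76 with a pseudocount of 0.01 and -0.83 to 2.10 without 1 replicate. With a pseudocount of 1, Chrng (-0.54) gave 0.055, Hbb-bt (-1.02) 0.36, Myf6 (-1.32) 0.079, Tbx1 (-1.38) 0.022 and Tnnt2 (-0.12) 0.49. Tnnt2 gave 0.019 without ribosomal protein genes. Without 1 replicate, Chrng ran from -1.44 to 0.92, Myh3 from -1.67 to 0.41, Tnnt2 from -1.87 to 1.55 and Isl1 from -0.51 to 1.84. Hbb-bt gave 0.20 without replicate 1 or 3. Without replicate 2, the only library where it was above 0, Hbb-bt was not tested.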

Other observations

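The gene families in this and the next paragraph were chosen after their values were seen, so their levels are not set against random lists. Of 31 SR and hnRNP protein genes, 30 were above 1 TPM by limma with Benjamini-Hochberg, with a median of 660 TPM. Hnrnph1 averaged 3638 ± 68.2 TPM and Hnrnpa1 2773 ± 312 TPM beside Srsf5 (± is SD, n = 3). Of 12 genes of the oxidative and metal stress response, 11 were above 1 TPM, with a median of 1732 TPM. The iron storage gene Fth1 averaged 3174 ± 8.21 TPM, the haem-degrading enzyme Hmox1 2907 ± 139 TPM, the metallothionein Mt2 2824 ± 560 TPM and the thioredoxin reductase Txnrd1 2321 ± 147 TPM, whereas Nqo1, at 1.89 ± 1.64 TPM, was not decided. Of 73 DnaJ and Hsp chaperone genes, 48 were above 1 TPM (median 25.0 TPM).

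The abundance of Cxcl1 was not shared by chemokines at large: of 35 Ccl and Cxcl genes, 15 were above 1 TPM by limma with Benjamini-Hochberg and 11 were listed at 0 in all libraries, with a median of 4.50 TPM. Cxcl2, its neighbour on chromosome 5, averaged 518 ± 46.6 TPM and Ccl7 80.4 ± 37.7 TPM. Of 13 circadian clock genes, 10 were above 1 TPM (median 71.1 TPM), with Arntl at 149 ± 20.98 TPM and Nr1d2 at 129 ± 9.20 TPM. Dbp, a clock output gene, was listed at 0 in all 3 libraries and Per3 at 0, 0.12 and 0 TPM. The neuropeptide gene Gal averaged 3726 ± 577 TPM, named after its values were seen.

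Genes at 0 in some libraries and above 0 in others were common: 1730 genes were at 0 in 1 library and 1973 in 2, and 144 of these averaged at least 10 TPM. The small nuclear ribonucleoprotein gene Snrpg was listed at 0, 35.0 and 26.9 TPM. Few reads per library is a candidate explanation: among genes of 5 to 20 TPM, 29.3% of the 1184 with the shortest exon length had a 0 against 3.55% of the 1184 with the longest, a ratio of 8.26. Reads shared between near-identical genes may add to this, since the odds of a 0 were 2.49 times higher (95% interval 1.79 to 3.47) for genes with at least 20% shared 31-base words than for genes with under 1%, compared within 3 classes of exon length. Gstp1 was at 0, 167 and 184 TPM and its neighbour Gstp2 at 130, 53.6 and 0 TPM. They share 67.5% and 78.1% of their words with any other annotated gene, and the share between Gstp1 and Gstp2 was not measured. No biological explanation was tested.

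The median spread between libraries fell with the level of the gene from the bin of 2 to 5 TPM upward. It was 2.80 at 1 to 2 TPM and 2.935 at 2 to 5 TPM (SD, log2 scale). Counting of reads is a candidate explanation: over 4904 genes of at least 20 TPM, log2 SD fell with log2 exon length at a given level, with a coefficient of -0.414 (95% interval -0.443 to -0.384). The coefficient of level was -0.433. The design has 1 group, so no biological explanation was tested.

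Fibro-adipogenic markers in the sorted cells may come from another cell type carried through the gate, although sorting on ZsGreen would remove cells without the reporter. The most abundant were Gsn at 888, Col3a1 at 585 and Dpt at 572 TPM, and satellite cells are themselves known to transcribe collagen genes. The 6 members not decided gave, in replicates 1 to 3, these values: Pdgfra at 4.98, 0.11 and 0.06 TPM, Lum at 8.58, 6.11 and 0.6, Mfap5 at 16.9, 13.4 and 0, Pi16 at 0, 8.9 and 3.36, Dpp4 at 2.52, 2.03 and 0.08, and Clec3b at 0.35, 4.57 and 0. A single source would move all its genes together between libraries, and the log2 ratios of replicate 1 to replicate 3 over the 9 members above 1 TPM, from -0.63 for Ly6a to 1.59 for Smoc2, had an SD at percentile 79.58 of 10000 level-matched lists. A large change between libraries itself makes a call above 1 TPM harder, so members such as Mfap5 were left out of that test. The percentile therefore cannot decide the question. With 9 genes in that test and 6 members not decided, contamination and transcription by satellite cells cannot be told apart.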
